A study of Mus musculus with 9 samples.

How the data were processed

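Total RNA of c-Kit-positive mouse bone marrow cells, taken with a bead kit from mice given pIpC, was measured by RNA sequencing in 9 libraries, 3 each of WT, Cbfb+/mDE and Cbfb+/MYH11 on the C57BL/6 strain. Per the labels, the processing used CASAVA 1.8.2, STAR 2.4, RSEM and DESeq2 on the GRCm38 build, with no role or order given. The deposited table holds 1 normalised signal value per gene and library, made by the authors from gene counts divided by a single size factor per library. It also holds a log2 fold change and an adjusted p-value per gene, which are log2 and p-value columns per the file headers, for a comparison the header does not name. These columns were used only in the closing section. The table lists 43629 genes, of which 17919 were 0 in all libraries. Symbols were found for 42462 of the gene identifiers (97.33%), and coordinates for 42548 in the GENCODE M21 annotation of GRCm38.

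Every deposited signal value was a whole multiple of the library's smallest nonzero value within a relative tolerance of 1e-06, so whole reads were recovered for 100% of values. The libraries held 39300366 to 50073097 reads. Where a gene has 0 reads in a library, a count of up to 3 reads was allowed, equal to 2.56 to 3.52 normalised reads, and this floor covers counting error only, as reads carry no molecular identifiers.

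The tests, the gene lists, the rule for named genes and the first set of alternatives were written before the data were examined. The design assumed counts with edgeR as the test, and named limma-trend on log2(value + 1) for values of another kind. As the table holds scaled values, limma-trend was the test used (limma 3.58.1, R 4.3.3, pseudocount 1). Genes were kept by filterByExpr (edgeR 4.0.16) on the recovered reads, which left 15948. All 9 libraries were fitted with genotype as the only term, leaving 6 residual degrees of freedom and 3.2 prior degrees of freedom. The 3 comparisons were MYH11 vs WT, mDE vs WT and MYH11 vs mDE, each with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. The tests are two-sided.

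Named genes were chosen by a rule fixed in the design. It takes Cbfb, Myh11, Runx1 and Kit always. It takes the 10 largest rises and 10 largest falls among genes with an adjusted p under 0.05, at least 5 CPM in the higher group and no overlap between the libraries of the compared groups. It takes up to 4 called members with the smallest adjusted p from each list with 3 or more called members or a camera adjusted p under 0.05. Gene models without a functional name and variable, diversity, joining and similar antigen receptor segments were skipped among the largest changes, which passed over 8 rises in mDE vs WT and 1 rise in each of the other comparisons.

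There were 25 gene lists, fixed from textbook knowledge. They covered the Cbfb-Runx complex, textbook Runx1-Cbfb targets, stem and multipotent progenitors, self-renewal factors, cytokine receptors, megakaryocytes, erythroid cells, early granulocytes, late neutrophils, monocytes, dendritic cells and MHC class II, mast cells, basophils and eosinophils, lymphoid priming, B cells, T and NK cells, stroma, cell cycle, CDK inhibitors and p53 targets, type I interferon, inflammation, immediate early genes, ribosome biogenesis, haem and iron, adhesion, and smooth muscle. Each list was tested with camera at a preset correlation of 0.01 on log2(value + 1), in place of the voom values the design named for counts, and adjusted over the 25 lists of a comparison. Camera with an estimated correlation and fry were run beside it, and list members were also adjusted over the list alone.

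The changes shared by the knock-in genotypes were set against 50 simulations of unchanged groups. All 9 libraries, WT included, were drawn around the WT means, independently for each gene, and both groups were compared with the same drawn WT libraries. The test was tested on simulated data with 100 genes changed 2-fold and 100 genes changed 4-fold per comparison. It recovered 64% to 68% of genes changed 2-fold and 90% to 93% of genes changed 4-fold, and called 7 to 9 unchanged genes. Counts were drawn independently for each gene, and far fewer genes changed than were called in the MYH11 comparisons, so these figures describe a simpler setting. The 1 raised list was called and 0 of 24 unchanged lists were called by camera in each comparison.

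The first set of alternatives was TMM, recomputed DESeq2 and upper-quartile scaling, no filter on low counts, a filter of 5 CPM in at least 3 libraries, the DESeq2 (1.42.0) Wald test and limma-voom on recovered reads, a fit of only the groups compared, the replicate number as a block, and leaving out each library in turn. Alternatives chosen after seeing the data were the edgeR quasi-likelihood test on recovered reads, pseudocounts of 0.5 and 4, and leaving clustered genes, genes near Cbfb and immunoglobulin segments out of the mDE vs WT count. edgeR on recovered reads called 9556, 188 and 8888 genes in the 3 comparisons.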

Results

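RNA was sequenced from mouse bone marrow cells selected for c-Kit (CD117), the stem cell factor receptor found on blood stem and progenitor cells. The mice had been given pIpC, a synthetic double-stranded RNA that induces interferon. The 9 libraries fell into 3 genotypes with 3 libraries each. WT mice carried the normal Cbfb gene. Cbfb+/MYH11 mice (MYH11 below) carried an allele encoding CBFβ-SMMHC, the fusion of the transcription factor subunit CBFβ with the tail of smooth muscle myosin heavy chain found in leukaemia with inv(16). Cbfb+/mDE mice (mDE below) carried a fusion allele altered in the C-terminal multimerization domain. Values are deposited normalised reads, given as mean ± SD of the 3 libraries of a genotype (n = 3), and the libraries held 39300366 to 50073097 reads. Fold differences are ratios of group means. The labels do not say that the libraries came from separate animals, so p-values measure only the spread between these samples, which may be technical.

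The genes joined in the fusion were read first. Cbfb (ENSMUSG00000031885, chromosome 8, 105170674 to 105217989 in GRCm38) stood at 6867 ± 305 normalised reads in WT, 5227 ± 481 in mDE and 6569 ± 299 in MYH11. Its level fell in mDE (log2 fold change -0.40, SE 0.07, limma adjusted p = 0.037) and did not pass the test in MYH11 (limma adjusted p = 0.461). The call of Cbfb, mDE vs WT, was lost when only the 2 groups were fitted (limma adjusted p = 0.0703) and without any of the 3 WT libraries, mDE replicate 1 or mDE replicate 2 (limma adjusted p from 0.0679 to 0.137). Myh11 (ENSMUSG00000018830, chromosome 16, 14194535 to 14291372), the smooth muscle myosin gene, rose from 7.02 ± 2.06 in WT to 37.9 ± 8.12 in mDE and 196 ± 21.3 in MYH11, 5.41-fold and 28.0-fold above WT (limma adjusted p = 0.00624 and 1.08e-06). All 6 knock-in libraries lay above every WT library. Runx1 (chromosome 16, 92601466 to 92826149), the DNA-binding partner of CBFβ, rose 2.24-fold in MYH11 to 6575 ± 919.6 from 2935 ± 97.6 in WT (limma adjusted p = 5.2e-06). Kit (chromosome 5, 75574916 to 75656722), which encodes the receptor used for selection, was 2.12-fold lower in MYH11, at 3538 ± 321 against 7504 ± 253 (limma adjusted p = 2.06e-06). In mDE neither passed the test, with Runx1 at 3580.2 ± 65.3 and Kit at 7256 ± 329 (limma adjusted p = 0.132 and 0.729).

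**Figure D1:**
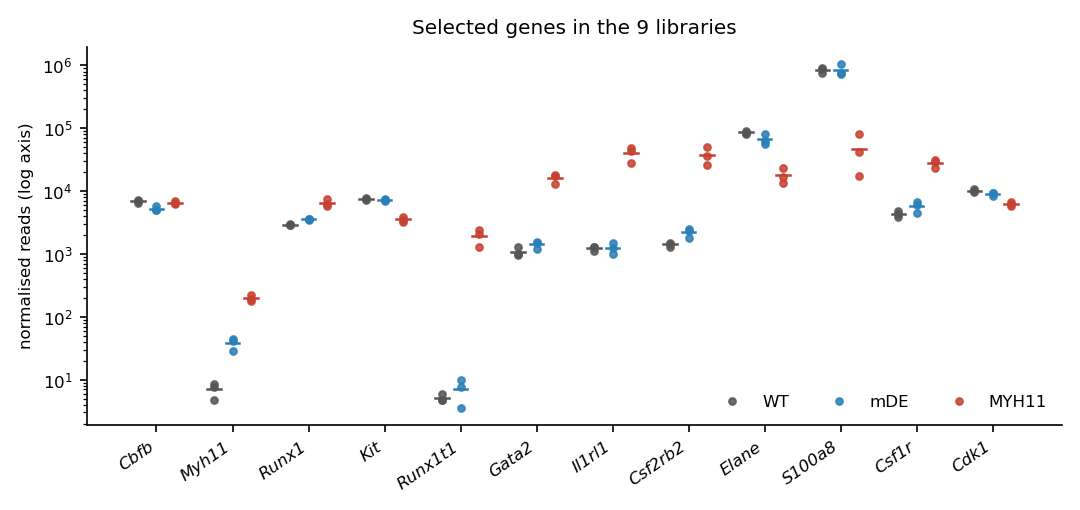
Normalised reads of 12 named genes (log axis) in each of the 9 libraries; points are libraries, coloured by genotype, and bars are means of 3 libraries. Myh11 lies higher in mDE than in WT and higher again in MYH11, while Runx1t1, Gata2 and Il1rl1 are high in MYH11 and S100a8 and Elane are low there.

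The first comparison asked which genes the full-length fusion allele changes in c-Kit-selected marrow cells. Mature neutrophil genes fell in MYH11, while many genes of monocytes and antigen-presenting cells rose. S100a8, an abundant calcium-binding protein of neutrophils, fell 18.1-fold, from 852889 ± 73508 to 47214 ± 32958 normalised reads (limma adjusted p = 3.47e-05). Gata2, a transcription factor of stem cells and mast cells, rose 15.0-fold, from 1074 ± 183 to 16133 ± 2681 (limma adjusted p = 2.45e-07). Il1rl1, the interleukin-33 receptor, rose 32.4-fold and Csf2rb2, a cytokine receptor beta chain, rose 26.4-fold (limma adjusted p = 2.45e-07 and 3.94e-07). Of 15948 genes tested, 9536 changed at a limma adjusted p under 0.05, 5105 up and 4431 down, and 3704 of them by at least 2-fold. The larger direction depended on the scaling, with 4648 up and 4898 down under TMM and 4368 up and 5304 down under upper-quartile scaling. The 3 libraries of each genotype did not overlap in 68.7% of genes, where chance gives 10%.

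The granulocyte lists fell. All 20 late neutrophil genes were lower (median log2 fold change -3.01, camera adjusted p = 1.8e-07), but the call was lost at an adjusted p = 0.701 with an estimated correlation. Ly6g, a neutrophil surface protein, fell 20.7-fold to 596 ± 409 and Camp, the antimicrobial peptide cathelicidin, fell 14.6-fold to 25659 ± 17072. Among 18 early granulocyte genes, which encode primary granule proteins and their regulators, 13 fell and 1 rose (camera adjusted p = 9.51e-05, and adjusted p = 0.701 with an estimated correlation). Elane, neutrophil elastase, fell 4.83-fold from 85805 ± 5059.6 to 17771 ± 4898, and Fcnb, a ficolin, fell 11.3-fold. The exception was Ctsc, the protease that activates granule enzymes, which rose 12.6-fold from 2725 ± 145 to 34228 ± 3446. The late neutrophil genes took 12.9% ± 1.2 of all reads in WT and 1.71% ± 0.898 in MYH11, and the 10 most abundant genes took 13.8% ± 1.03 and 4.90% ± 0.22. In the plot of marker shares the MYH11 libraries ranged from 0.887% to 2.67% late neutrophil reads.

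**Figure D2:**
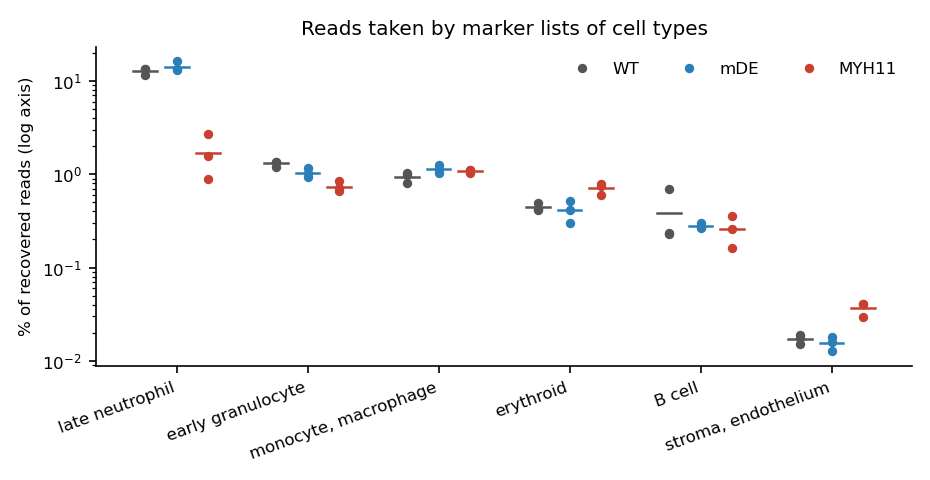
Percent of recovered reads (log axis) taken by the genes of 6 cell type lists in each of the 9 libraries; points are libraries and bars are means of 3 libraries. The late neutrophil share is 11.5% to 13.6% in WT, 13.1% to 16.2% in mDE and 0.887% to 2.67% in MYH11.

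Monocyte and antigen presentation genes rose. Of 25 monocyte and macrophage genes, 19 rose and 4 fell (median log2 fold change 1.82, camera adjusted p = 0.000222, and adjusted p = 0.701 with an estimated correlation). The genes of this list together took 0.938% ± 0.113 of reads in WT, 1.14% ± 0.108 in mDE and 1.08% ± 0.0406 in MYH11. S100a4 rose 21.7-fold, F13a1, coagulation factor XIII A chain, rose 7.97-fold to 69148 ± 4945, and Klf4, a transcription factor of monocytes, rose 5.96-fold. Of 20 dendritic cell and MHC class II genes, 17 rose and 2 fell (median 2.06, camera adjusted p = 0.000222, and adjusted p = 0.701 with an estimated correlation). Ciita, the master regulator of MHC class II genes, rose 15.3-fold from 239 ± 36.1 to 3659.9 ± 501, and H2-DMa rose 4.37-fold. Both lists rose in the same libraries in which the late neutrophil share of reads was lowest.

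Of 21 mast cell, basophil and eosinophil genes, 12 rose and 6 fell, and the list as a whole did not pass (median 1.75, camera adjusted p = 0.0854). It holds genes of all 3 cell types, and many of them are shared by mast cells and basophils. Ms4a2, the beta chain of the IgE receptor, rose 29.4-fold to 27613 ± 4913 from 938 ± 86.3, and Cd200r3 rose 42.4-fold. The members that fell were Prss34 and Mcpt8, proteases of basophils, Prg2, Prg3 and Epx, granule proteins of eosinophils, and Hdc, which makes histamine; these were named after their values were seen. The mast cell protease genes Mcpt1 and Mcpt2 were among the 10 largest rises. Mcpt1 went from 7.07 ± 11.4 to 18665 ± 2317 and Mcpt2 from 3.10 ± 0.368 to 2245 ± 393 (limma adjusted p = 4.49e-06 and 3.17e-07).

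The other large rises were of Tph1, which starts serotonin synthesis, at 8766 ± 4363 in MYH11, Retnla at 15266 ± 7592, the chemokine Ccl24 at 6614 ± 2395, Maob at 4821 ± 1679.9, Gsg1l at 2674 ± 514, the signalling protein Wnt2 at 2472 ± 729 and C2cd4a at 1301 ± 213. In WT these 7 genes averaged from 0.643 (Wnt2) to 20.6 (Retnla) normalised reads. Dnase2b, at 489.7 ± 136 in MYH11, had no read in any WT library, which allows up to 3 reads a library (2.88 to 3.52 normalised reads). The largest falls among named genes were of Ear6, an eosinophil-associated ribonuclease, from 1477 ± 778 to 0.301 ± 0.522, Sh3tc2 from 942 ± 60.9 to 1.18 ± 0.542, the retinal dehydrogenases Aldh1a7 (143-fold) and Aldh1a1 (65.6-fold), the tight junction protein Cldn1 (115-fold), Acsl6 (90.4-fold), Spon2 (89.6-fold), Prss50 (73.1-fold), Sh2d4a (64.9-fold) and Tesc (62.4-fold). Acsl6, Spon2, Prss50 and Tesc held only 14, 14, 17 and 18 reads in the MYH11 libraries together, so the size of their falls is uncertain. Reads of the Mcpt, Ear, Aldh1a, Csf2rb and alpha globin genes can be split between near-identical family members, so their single values are uncertain.

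Of 13 members of the Cbfb-Runx complex list, 8 rose and 1 fell (median 0.34, camera adjusted p = 0.0237, and adjusted p = 0.701 with an estimated correlation). The list holds Cbfb and Myh11, the genes joined in the fusion, and Myh11 counts among the 8 rises. The call also ended with the stricter count filter, which Myh11 does not pass. It therefore does not speak for the other members alone. Runx1t1, the corepressor known as ETO, rose 373-fold from 5.17 ± 0.613 to 1928 ± 570.2, and Cbfa2t3, of the same family, rose 3.85-fold. Textbook targets of Runx1 and CBFβ went both ways, 4 up and 9 down of 15 (camera adjusted p = 0.298). Csf1r, the receptor for the macrophage growth factor, rose 6.44-fold and Prkcq 19.6-fold, while Cebpe, a granulocyte transcription factor, fell 9.64-fold. Of 24 stem and multipotent progenitor genes 13 rose, among them Tek (23.4-fold) and Hlf (4.43-fold), and 4 fell (camera adjusted p = 0.0723). Of 20 self-renewal and leukaemia-associated transcription factors 8 rose, such as Ikzf2 (12.3-fold) and Sox4 (2.13-fold), and 2 fell, Myb (1.53-fold) and Erg (1.57-fold), with a camera adjusted p = 0.298. Of 25 cytokine receptor genes 13 rose and 10 fell (camera adjusted p = 0.298).

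Cell cycle genes fell by small amounts. Of 30, 27 were lower and 0 higher (median -0.47, camera adjusted p = 1.43e-08, and adjusted p = 0.701 with an estimated correlation), 28 of them lower when adjusted over the list alone. Rrm2, a subunit of ribonucleotide reductase, fell 1.89-fold, Cdk1 1.62-fold, Mcm5 1.53-fold and Ccne1, cyclin E1, 2.58-fold. Among CDK inhibitors and p53 targets 10 of 24 rose, with Cdkn1a up 4.95-fold and Phlda3 up 17.5-fold, and 5 fell (camera adjusted p = 0.347). The lists that follow did not pass the list test, with camera adjusted p from 0.0723 to 0.99. In the erythroid list 10 of 29 rose, led by Alas2 of haem synthesis (15.3-fold) and the alpha globin gene Hba-a1 (8.61-fold), and 10 fell, such as the water channel Aqp1 (9.42-fold). In the haem and iron list 11 of 23 rose and 9 fell. In the megakaryocyte and platelet list 11 of 23 rose, such as Gp1ba (12.9-fold) and Mrvi1 (59.9-fold), and 9 fell; its median (-0.05) and mean (0.52) had opposite signs. Of 19 lymphoid priming genes 12 rose, among them Flt3 (2.99-fold), and 4 fell. In the B cell list 11 of 26 fell, such as Ms4a1 (18.5-fold) and Blk (13.7-fold), and 3 rose. In the T and NK cell list 5 of 28 rose, with Gata3 up 31.9-fold, and 6 fell, with Ncr1 down 13.3-fold. Type I interferon genes went 13 up and 5 down of 30, inflammatory genes 13 up and 5 down of 23, immediate early genes 2 up and 5 down of 20, and ribosome biogenesis genes 1 up and 10 down of 24. Adhesion genes went 5 up and 7 down of 21, with Itgb7 up 9.47-fold and Cxcr4 down 2.41-fold, stroma and endothelium genes 5 up and 5 down of 17, and smooth muscle and actomyosin genes 6 up and 8 down of 17, with a median of -0.42 and a mean of 0.07.

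**Figure D3:**
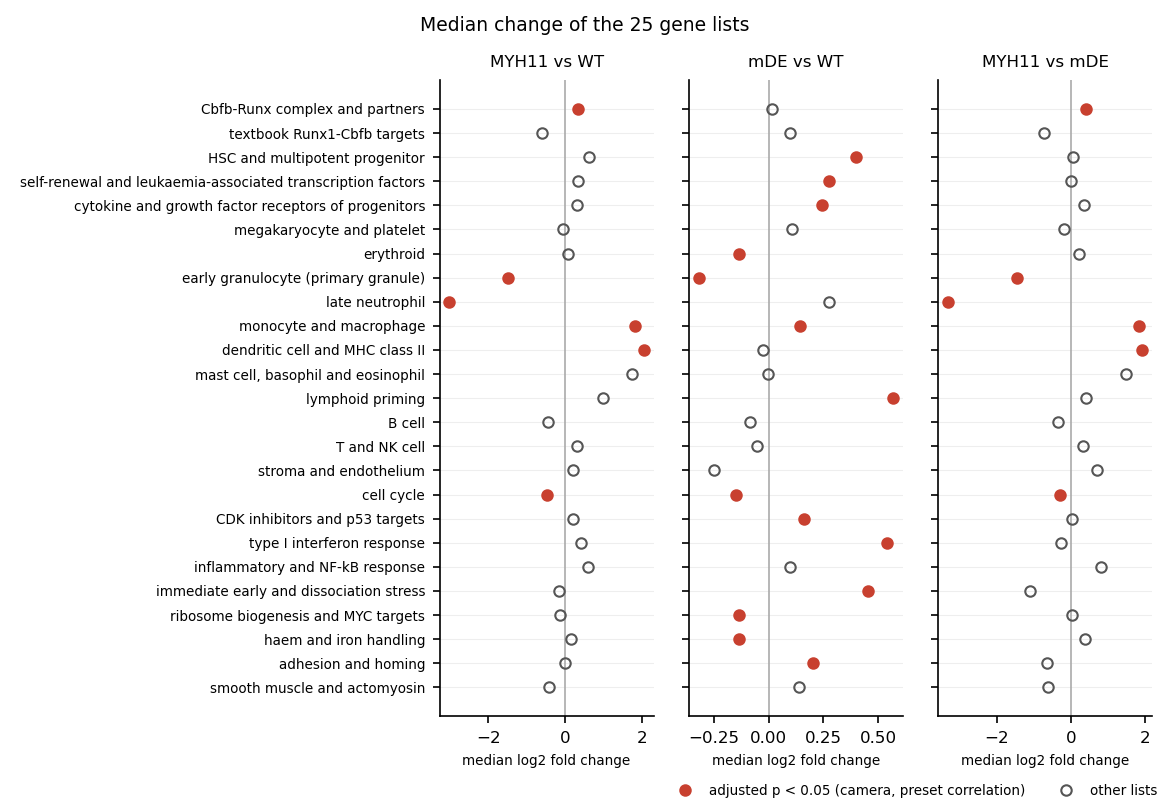
Median log2 fold change of the tested members of the 25 gene lists in the 3 comparisons, each with its own horizontal axis; filled points mark a camera adjusted p under 0.05 at the preset correlation. The late neutrophil median is -3.01 in MYH11 vs WT, 0.28 in mDE vs WT and -3.33 in MYH11 vs mDE.

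The second comparison asked what remains of these changes with the altered multimerization domain. In mDE vs WT, 198 of 15948 genes passed a limma adjusted p under 0.05, 131 up and 67 down, and 84 by at least 2-fold. At an unadjusted p under 0.05 limma gave 3160 genes, and the 3 libraries of each genotype did not overlap in 26.1% of genes, where chance gives 10%. Fn1, fibronectin, rose 3.87-fold from 567 ± 77.8 to 2194 ± 371 (limma adjusted p = 0.000442). Flt3, a cytokine receptor of early progenitors, rose 2.07-fold to 1382 ± 251, and Dntt, the terminal transferase of lymphoid progenitors, rose 2.46-fold to 3214 ± 573 (limma adjusted p = 0.022 and 0.0308). Siglech, a surface protein of plasmacytoid dendritic cells, rose 3.35-fold. The late neutrophil list did not pass (median log2 fold change 0.28, camera adjusted p = 0.0847, 20 genes), and its genes took 14.2% ± 1.69 of reads in mDE. Monocyte genes S100a4 (2.38-fold), Klf4 (1.52-fold) and F13a1 (1.45-fold) rose, and the early granulocyte gene Cst7 fell 1.45-fold.

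The largest rise in mDE among named genes was of the inflammasome sensor Nlrp1b, from 27.3 ± 9.36 to 403 ± 13.5 (14.8-fold, limma adjusted p = 0.000154). Its neighbour Nlrp1a, named after its values were seen, fell from 256 to 171 normalised reads (limma adjusted p = 0.036). Both lie among the clustered genes described below. Gene models without a functional name, which the naming rule leaves out, also rose. Gm6472, Gm10020, Gm4737 and Rpl15-ps2 had log2 fold changes of 2.65, 3.53, 4.65 and 3.14 (limma adjusted p from 4.05e-05 to 0.000452). Gm6472 had the smallest adjusted p of the comparison. None of these gene models was called in MYH11 vs WT, and the cause was not tested. Eif3j2, a translation initiation factor subunit with the near-identical copy Eif3j1, rose 6.85-fold, from 126 to 862 normalised reads. Eif3j1, named after its values were seen, stood at 1934 in mDE against 3100 in WT, so reads can be split between these copies. The interferon-induced genes Ifi44 and Xaf1 rose 6.43-fold and 4.17-fold. Ifi44 lies among the clustered genes, beside Ifi44l and Ptgfr, which were also higher in mDE. Further rises were of Fam71b (3.52-fold), Zfp467 (2.49-fold), Ppp1r9a (2.41-fold), Mn1, a transcription coregulator, (3.22-fold) and Perp, a p53 target (2.06-fold). The largest falls among named genes were of the immunoglobulin constant genes Ighg2c, from 2176 ± 1127 to 15.3 ± 12.5, and Ighg3, from 1848 ± 967 to 221 ± 115. Tjp1, a tight junction protein, fell 3.31-fold from 647 ± 41.1 to 196 ± 32.2, and the integrin gene Itga6 fell 2.27-fold. Dmc1 and Rec8, proteins of meiotic chromosomes, fell 3.08-fold and 2.57-fold, Bdh1 2.26-fold, Tango6 2.10-fold, Smim6 1.87-fold, Arhgap31 1.73-fold and Pcna, the DNA polymerase clamp, 1.27-fold. Pcna stood at 16437 normalised reads in mDE against 20877 in WT, while its copy Pcna-ps2, named after its values were seen, stood at 2097 against 374, so reads of the pair can be split between them. These falls carried limma adjusted p from 0.000373 (Tango6) to 0.037. Among 177 called genes off chromosome 8 and outside antigen receptor segments, 67 lay within 1 Mb of another called gene, and Tango6 lies 1.57 Mb from Cbfb.

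In mDE the list test called 14 of 25 lists at the preset correlation, 9 up and 5 down, although few single members passed, and none of the 14 was called with an estimated correlation. Lymphoid priming genes had a median log2 fold change of 0.57, with 2 of 19 members called over all genes and 7 adjusted over the list alone (camera adjusted p = 8.48e-06, and adjusted p = 0.45 with an estimated correlation). Type I interferon genes had a median of 0.54, 2 of 30 called and 9 adjusted over the list alone (camera adjusted p = 2.6e-07, and adjusted p = 0.64 with an estimated correlation). Stem and multipotent progenitor genes had a median of 0.40, 0 of 24 called and 4 adjusted over the list alone (camera adjusted p = 0.000327, and adjusted p = 0.45 with an estimated correlation). The self-renewal, cytokine receptor, monocyte, CDK inhibitor, immediate early and adhesion lists were the other called lists with a positive direction, with medians from 0.14 (monocyte) to 0.45 (immediate early), 3, 1, 1 and 1 members called up in the monocyte, self-renewal, cytokine receptor and CDK inhibitor lists, and adjusted p from 0.45 to 0.658 with an estimated correlation. The adhesion list had no member called up and 1 called down, Itga6, with 4 up and 1 down adjusted over the list alone. The called lists with a negative direction were cell cycle (median -0.15, 1 of 30 called, which was Pcna, 9 adjusted over the list alone, camera adjusted p = 1.18e-08), ribosome biogenesis (median -0.13, none called, 4 adjusted over the list alone, camera adjusted p = 2.99e-08), early granulocyte (median -0.32, camera adjusted p = 0.000383), erythroid (median -0.13, camera adjusted p = 0.0485) and haem and iron (median -0.14, camera adjusted p = 0.0485). With an estimated correlation their adjusted p was 0.45, 0.45, 0.568, 0.748 and 0.658. The other 11 lists did not pass (camera adjusted p from 0.0847 to 0.595), and the dendritic cell and MHC class II list had a median of -0.02 and a mean of 0.09.

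The number of genes called in mDE vs WT depended on single libraries and on the test. It was 941 with DESeq2, 125 without genes that lie in clusters, near Cbfb or in immunoglobulin segments, 123 with only the 2 groups fitted or with the stricter count filter, 89, 32 and 39 without WT replicates 1, 2 and 3, and 123 and 90 without mDE replicates 2 and 3. The share of rises was 66.2%, against 55.3% with upper-quartile scaling and 53.1% with limma-voom, and 88.8%, 78.1% and 84.6% without WT replicates 1, 2 and 3, where 10, 7 and 6 genes fell. Of the 30 named genes called, 20 lost their call in at least 1 alternative that fitted genotype alone. The other 10 kept it in every such alternative that tested them, and the stricter count filter did not test Myh11. The 10 were Myh11, Nlrp1b, Eif3j2, Xaf1, Fn1, Zfp467, Tjp1, Rec8, Tango6 and Arhgap31. Of these, Nlrp1b, Eif3j2, Zfp467, Rec8 and Arhgap31 lie among the clustered genes and Tango6 lies near Cbfb. A call kept under other fits does not show what caused it. The count of called lists was 8 without WT replicate 1 and 9 without mDE replicate 2. The calls of the erythroid and the haem and iron lists ended under TMM, recomputed DESeq2 and upper-quartile scaling, with the stricter count filter, DESeq2, limma-voom or edgeR, with only the 2 groups fitted and with a pseudocount of 0.5. Those of the CDK inhibitor and adhesion lists ended with recomputed DESeq2 scaling, edgeR or a pseudocount of 0.5, the first also with limma-voom and the second with the stricter filter or DESeq2. Without single libraries, the erythroid call ended without WT replicate 1, mDE replicate 2 or mDE replicate 3, the haem and iron call without these or WT replicate 2, the adhesion call without the same 3 as the erythroid call, and the CDK inhibitor call without any of the 6. That of the monocyte list ended with only the 2 groups fitted and without WT replicate 1 or mDE replicate 3, and that of the immediate early list without WT replicate 1 or mDE replicate 2.

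The third comparison set the 2 knock-in genotypes against each other and so tests directly whether the change from WT differed between them. The late neutrophil genes were low in MYH11 against mDE as well, and most monocyte and MHC class II genes were high. Il1rl1 was 32.1-fold higher in MYH11 than in mDE (1249 ± 241 in mDE), Gata2 11.3-fold higher, Runx1t1 273-fold higher, and S100a8 17.9-fold lower (845293 ± 176798 in mDE), with limma adjusted p = 3.75e-07, 5.31e-07, 5.12e-07 and 4e-05. Kit was 2.05-fold lower and Runx1 1.84-fold higher in MYH11 (limma adjusted p = 3.23e-06 and 3.14e-05), Cbfb was 1.26-fold higher and Myh11 5.18-fold higher (limma adjusted p = 0.00317 and 5.91e-05). Outside the genes already named for MYH11 vs WT, the 10 largest rises held Gkn3 (616 ± 113 in MYH11 and 0.365 ± 0.632 in mDE) and the 10 largest falls held Fam71b (2.61 ± 1.43 and 366 ± 55.6). In all, 8869 genes differed at a limma adjusted p under 0.05, 4718 higher and 4151 lower in MYH11, and 3525 by at least 2-fold. The larger direction turned with the scaling here too, to 4422 higher and 4429 lower under TMM and 4166 higher and 4733 lower under upper-quartile scaling. The libraries of the 2 genotypes did not overlap in 62.2% of genes, where chance gives 10%.

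The list test called 6 lists between the knock-in genotypes. Late neutrophil genes were lower in MYH11 in 20 of 20 members (median -3.33, camera adjusted p = 1.63e-08) and early granulocyte genes in 13 of 18 (median -1.46, camera adjusted p = 0.00217), with the late neutrophil reads at 14.2% ± 1.69 in mDE and 1.71% ± 0.898 in MYH11. Monocyte genes were higher in 18 of 25 (median 1.85, camera adjusted p = 0.000575), dendritic cell and MHC class II genes in 15 of 20 (median 1.93, camera adjusted p = 0.000413) and the Cbfb-Runx list in 9 of 13 (median 0.41, camera adjusted p = 0.0122). The Cbfb-Runx list holds Cbfb and Myh11, the genes joined in the fusion, and both count among the 9. Cell cycle genes were lower in 24 of 30 (median -0.29, camera adjusted p = 6.13e-06). All 6 calls were lost with an estimated correlation, at an adjusted p = 0.75 for the early granulocyte list and 0.743 for the other 5 lists. Of the mast cell, basophil and eosinophil list 12 of 21 were higher and 6 lower (camera adjusted p = 0.069). Stem and multipotent progenitor genes were higher in 7 and lower in 3 of 24 (camera adjusted p = 0.612), lymphoid priming genes higher in 8 and lower in 4 of 19 (camera adjusted p = 0.607), and type I interferon genes higher in 5 and lower in 9 of 30 (camera adjusted p = 0.444).

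The changes from WT of the 2 knock-in genotypes were then compared with each other. Of the 198 genes called in mDE vs WT, 157 were also called in MYH11 vs WT, 133 in the same direction and 24 in the opposite one. Fn1, Nlrp1b, Flt3, S100a4 and Tango6 were among those called in the same direction in both, and Tjp1, Rec8, Itga6 and Arhgap31 fell in mDE and rose in MYH11. Among these named genes, Nlrp1b, Rec8, Itga6 and Arhgap31 lie among the clustered genes described below, and Tango6 lies near Cbfb. Of the 133, 94 rose and 39 fell in both, where independent lists of these sizes would share 41.9 and 18.6, but the comparisons share their WT libraries and so are not independent. Of the 24, 12 rose in MYH11 and fell in mDE and 12 did the reverse, where independent lists would share 21.45 and 36.4. The log2 fold changes correlated across 15948 genes, which are not independent replicates, with r = 0.24. The median was 0.51 in 50 simulations of unchanged groups set against shared WT libraries, all drawn around the WT means. The 2 changes had the same sign in 62.9% of genes, against 66.9% (66.1% to 67.7%) in these simulations. Changes in one genotype alone lower both measures, so values below the simulated ones do not tell whether changes were shared. The covariance of the changes was 0.134, against 0.041 in these simulations, a difference of 0.093. Genes were drawn independently there, while real genes varied together, with an estimated correlation of 0.863 in the late neutrophil list. The simulated range is thus no fair bound, and the difference does not tell whether changes were shared. The numbers called in both depended on the test and on single libraries. They were 42 up and 48 down with limma-voom, 399 and 232 with DESeq2, 60 and 24 with the stricter count filter and 74 and 60 with upper-quartile scaling. They were 58 up and 5 down, 11 and 3, and 16 and 2 without WT replicates 1, 2 and 3. Without mDE replicates 1, 2 and 3 they were 110 up and 25 down, 40 and 24, and 35 and 15. Without MYH11 replicates 1, 2 and 3 they were 39 up and 12 down, 110 and 57, and 45 and 19.

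**Figure D4:**
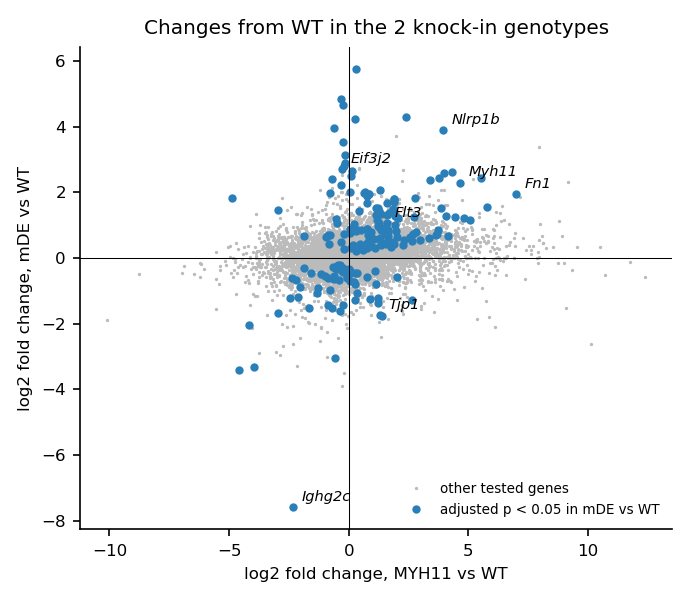
Fitted log2 fold change of each tested gene in mDE vs WT (vertical axis) against MYH11 vs WT (horizontal axis); blue points are the 198 genes called in mDE vs WT. Fn1, Nlrp1b and Myh11 lie in the upper right, Tjp1 lies below 0 in mDE and above 0 in MYH11, and Ighg2c is the lowest point.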

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

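The counts over other splits of the libraries were planned, and the correlations and fits set against the deposited comparison columns were chosen after those columns had been seen.

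The authors' deposited table holds a comparison that names no groups and that the report does not use, with an adjusted p under 0.05 for 7710 genes, 4654 with a negative and 3056 with a positive log2 fold change. Over 15948 genes, which are not independent replicates, the log2 fold changes of the authors' deposited table correlated with those of MYH11 vs WT at r = -0.9, of MYH11 vs mDE at r = -0.805 and of mDE vs WT at r = -0.357. Of the 7710 genes in the authors' deposited table, 6240 were also called in MYH11 vs WT by limma. These correlations do not identify the comparison. With the sign turned, the log2 fold changes of the authors' deposited table lay within 0.1 of a DESeq2 fit on the recovered reads for 30.4% of genes in MYH11 vs WT, 23.66% in mDE vs WT, 26.42% in MYH11 vs mDE and 51.35% with both knock-in genotypes together against WT, so none of these 4 fits matched it.

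The 6 libraries of each comparison make 10 splits into groups of 3, too few for a share under 0.05, and 1 of the 10 splits, the real one, gave as many genes in each comparison. In MYH11 vs WT the real split gave 9536 genes and the highest other split 0. In mDE vs WT the values were 198 and 1, and in MYH11 vs mDE they were 8869 and 0.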

How the results depend on the processing

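Alternatives with edgeR, another pseudocount or clustered genes left out were chosen after seeing the data. In MYH11 vs WT and MYH11 vs mDE all 116 and 118 called named genes kept direction and call in every alternative that tested them. The number of genes without 1 library ranged from 8355 to 9080 in MYH11 vs WT and from 7679 to 8549 in MYH11 vs mDE. In mDE vs WT it was 198, against 123 with the stricter count filter, where fewer genes were tested, 123 with only the 2 groups fitted, 941 with DESeq2 (185 of the 198 shared), and 125 (89 up and 36 down) with clustered genes, genes near Cbfb and immunoglobulin segments left out by construction. Without 1 library it ranged from 32 (without WT replicate 2) to 207 (without mDE replicate 1). Rises were 66.16% of these calls, 55.28% with upper-quartile scaling. Apart from the stricter filter and the genes left out, the cause was not tested.

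Of 25 lists, 6 were called in MYH11 vs WT, against 10 with TMM, 11 with upper-quartile scaling, 11 with no filter, 10 with DESeq2, 15 with fry, 5 with the stricter filter and 0 with an estimated correlation. In mDE vs WT 14 were called, against 0 with fry (lowest adjusted p 0.0764) and 0 with an estimated correlation (lowest 0.45), 10 with recomputed DESeq2 scaling, edgeR or a pseudocount of 0.5 and 11 with the stricter filter, DESeq2 or limma-voom, and in MYH11 vs mDE 6, against 12 with fry and 0 with an estimated correlation. Without 1 library the lists called ranged from 6 to 9 in MYH11 vs WT, 8 to 16 in mDE vs WT and 6 to 8 in MYH11 vs mDE. The mean log2 fold change of list erythroid, mDE vs WT, ranged from -0.3037 (without mDE replicate 1) to 0.0551 (without mDE replicate 3), where it turned. The correlation between the changes of the knock-in genotypes was 0.2444 and ranged from 0.2133 to 0.2899 without 1 library. The cause was not tested.

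Libraries with the same replicate number shared only the number, with correlations of their deviations from -0.1468 to 0.1245, and not every library correlated best with its own number. With the number as a block, 9452, 101 and 8786 genes were called in MYH11 vs WT, mDE vs WT and MYH11 vs mDE, and 6, 14 and 8 lists, with a correlation of 0.2444 between the knock-in changes and 43 genes up and 18 down in both. The block ended 11 calls of named genes in mDE vs WT and none in the other comparisons, by limma. Depth limits genes with few reads, where 3 reads a library equal 2.56 to 3.52 normalised reads.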

Other observations

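The tests on the position of called genes in clusters, on Myh11 above WT in the knock-in libraries and on the cell cycle list against the neutrophil share were chosen only after the results were seen, as were the paired and single genes named in this part.

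Other cell types and signs of sample make-up gave the following values. Erythroid genes took 0.445% ± 0.0434 of reads in WT, 0.411% ± 0.109 in mDE and 0.712% ± 0.1 in MYH11, and stroma and endothelium genes took 0.0173% ± 0.00191, 0.0156% ± 0.00272 and 0.0369% ± 0.0065. Early granulocyte genes took 1.31% ± 0.0892, 1.04% ± 0.123 and 0.737% ± 0.0912. B cell genes took 0.386% ± 0.266, 0.28% ± 0.0178 and 0.258% ± 0.0955, and mitochondrial genes 1.57% ± 0.0467, 1.74% ± 0.0953 and 1.92% ± 0.12. Xist, transcribed from an inactive X chromosome, had 7704 to 9756 reads in WT, 3607 to 12495 in mDE and 20878 to 41922 in MYH11, while the Y-linked genes Ddx3y, Kdm5d, Eif2s3y and Uty had 0 or 1 read in each library. WT replicate 1 held 20.3 normalised reads of Mcpt1, 10.6 of Tph1 and 48.2 of Retnla, against 0 to 11.7 in WT replicates 2 and 3.

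Genes changed in mDE vs WT lay in clusters. Of 177 called genes off chromosome 8 and outside antigen receptor segments, 67 (37.85%) had another called gene within 1 Mb, against a median of 24.86% and a 95th percentile of 31.64% in 10000 random draws (permutation p = 0.002, one-sided) and 32.77% among the 177 genes of smallest p in MYH11 vs WT. Eif3j1 stood at 1934 normalised reads in mDE against 3100 in WT while Eif3j2 stood at 862 against 126, Pcna at 16437 against 20877 with Pcna-ps2 at 2097 against 374, and the neighbours Ifi44, Ifi44l and Ptgfr on chromosome 3 were all higher in mDE. Local effects or strain DNA linked to the targeted Cbfb locus are argued against as the source of the set, since 194 called genes lay elsewhere. Within 10 Mb of Cbfb, 2 of 148 tested genes were called (1.35%, Tango6 and Cmtm3), against 1.24% elsewhere (one-sided Fisher exact p = 0.549). For these 2 genes a linked effect stays open. Tango6 lies 1.57 Mb and Cmtm3 0.85 Mb from Cbfb, and both were called in the same direction in MYH11. The MYH11 vs WT genes also lay above the 95th percentile of the draws, and the gap between 37.85% and 32.77% was not tested. No strain variants were examined. Immunoglobulin genes such as Ighg2c and Ighg3 were left out of the cluster count, so it does not speak for their falls, and a DNA difference there stays open. DNA segments of another strain elsewhere in the genome may account for part of the mDE calls, but a genotype effect and reads shared between paralogs stay open as well.

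Myh11 stood above every WT library in 6 of 6 knock-in libraries. Smooth muscle cells carried along were predicted to raise the smooth muscle markers. In MYH11 the median log2 fold change of the 4 tested markers was -0.72, with Acta2 at -1.25, Smtn at -1.20, Tagln at -0.24 and Cnn1 at 3.71. This median cannot decide, because Acta2, Smtn and Tagln stood at 300, 1685 and 193 normalised reads in WT, against 7.02 for Myh11. Such levels can come from other cells and hide a small rise. Cnn1, at 5.28 in WT, rose with Myh11. Des, Lmod1 and Myl9 did not pass the count filter and showed no rise like that of Cnn1. They stood at 0.892, 0.597 and 7.83 in MYH11, against 0.322, 0 and 4.38 in WT. The low markers thus differ, and levels near the floor decide little, so smooth muscle cells carried along stay open. Reads of the fusion transcript counted at Myh11 may give the Myh11 level. They cannot be told apart from transcription of the mouse gene itself, because the table holds 1 value per gene. Myh11 was lower in mDE than in MYH11, and whether that reflects transcript level, stability or a different share of expressing cells was not tested.

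The genes changed in MYH11 came from libraries that held less neutrophil RNA. A lower share of neutrophils carried along would shift the genes of all other cells alike, and the size factors can absorb such a shift. A rise of these genes could therefore hardly appear. This explanation is argued against as the whole cause only because the other genes did not move alike. The cell cycle list (median log2 fold change -0.47) and Kit fell while the monocyte list rose (median 1.82). The amount of late neutrophil RNA cannot be told apart from a change of the early granulocyte genes themselves. The highest early granulocyte mean log2 level in MYH11 was 12.94 against 13.88 in the lowest WT library, but the late neutrophil levels (12.29 to 14.09) also lay below every WT library (15.80 to 16.32), so the bound set beforehand was no fair test. A change of cell types by genotype stays open and was not tested apart from a change within cells.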
